A study of Homo sapiens with 6 samples.

How the data were processed

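RNA was measured in 6 libraries of BT-474 cells, 3 transfected with negative control siRNA and 3 with HER2 siRNA, and groups and replicate numbers were taken from the sample titles. Per the labels' protocols, HER2 siRNAs were used at 15 nM with 7.5 µL of Lipofectamine RNAiMax per well, and 2 siRNAs were named for each target; the labels do not say which siRNA or pool went into which library, so replicates may differ in siRNA. RNA was isolated on RNeasy columns with a DNase step, and libraries of total RNA were made with a ScriptSeq Complete Gold kit, which removes ribosomal RNA, per the labels' protocols. The authors deposited 2 tables per library, and the unit of both is FPKM, fragments scaled to transcript length and to the mapped fragments of the library. FPKM values were made with TopHat (version not given) and Cufflinks 2.0.2 on build hg19, per the submitters' processing notes. The transcript annotation, the strand setting, any filter and which fragments made up that total are not given in the sources used here. FPKM divides by the total, so a few abundant genes that rise lower the values of all others.

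Genes of the mRNA tables are given by symbol, and lincRNAs by locus identifier without a name. Of the 23672 symbols, 22346 (94.4%) were matched to the RefSeq table of GRCh38.p14. That table was used only for gene types and for which genes neighbour or contain each other. The genes that contain small nucleolar RNA genes were found from its coordinates, and no other coordinates were used. No reads or counts were used here, and absolute depth is unknown. Relative depth between libraries was estimated from the ratio of FPKM at genes below 0.05 FPKM in every library, where single reads form steps, as the most frequent log2 ratio in bins of 0.02; these estimates closed to within 0.01 on the log2 scale around triples of libraries. No 2 libraries held the same values.

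The main test was limma 3.58.1 (R 4.3.3), with empirical Bayes variance and a mean trend, on log2(FPKM + 1) of genes with a mean of at least 1 FPKM over the 6 libraries, and on log2(FPKM + 0.1) of lincRNAs with a mean of at least 0.3 FPKM, fitted apart. It was two-sided, without covariates, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on these log scales, which understates the change of genes near or below the pseudocount, and are HER2 siRNA minus control. FPKM is not a count, so no count model was used. ERBB2 was also tested with a two-sided exact permutation test. Gene lists were fixed before the data were examined, 26 in all, and the 21 with at least 5 tested members, the list of noncoding RNAs aside, were tested with camera, with a preset correlation of 0.01 between genes, which compares a list with the other genes. Camera with an estimated correlation and fry, which tests whether a list moves on balance 1 way, were alternatives; with the former 0 lists were called, 3 had an unadjusted p under 0.05, and fry called 13.

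A rule for named genes was fixed before the data were examined. It took ERBB2, the 10 largest rises and 10 largest falls among called mRNAs whose groups did not overlap, the 6 largest lincRNA rises and falls by the same rule (of which 2 identifiers per direction are printed), up to 4 members of each list with the smallest p, and every tested member of the HER family. Members added to complete a count of 5 or fewer were named after their values were seen, and not every such count is completed. EGFR and ERBB4 are named only as untested. Histone, ribosomal protein and cystatin genes have near-identical copies that share reads, so single members are uncertain.

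The test was run on simulated data made from the control means and the spread of these libraries. Among 9345 simulated mRNAs with 200 changed, 71.6%, 98.5% and 100% of genes changed by a log2 fold of 0.5, 1 and 2 were recovered, with 14 false calls. Among 500 simulated lincRNAs with 100 changed, 11.8%, 51.5% and 78.8% were recovered, with 3 false calls. LincRNA changes by a log2 fold of 1 or less were often missed at this depth and number of libraries, and some of 2. In a simulation that lowered the glycolysis list by a log2 value of 0.5, camera called that list and no other of 21. The simulated genes varied independently, whereas the correlation estimated for this list in the data was 0.417. The simulation therefore cannot show how often correlation between genes leads to false list calls.

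Alternatives were another pseudocount (0.1 for mRNAs, 1 for lincRNAs), no filter or a stricter filter (5 and 1 FPKM), quantile normalisation, upper-quartile scaling, the variance prior without a trend or made robust, the replicate number as a block, and leaving out each library. Protein-coding genes alone, and lincRNAs scaled by the upper quartile of the mRNA table, were added after the data had been seen. XIST and Y-linked genes are not reported. The values of some other single list members are not reported here.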

Results

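The series compared RNA levels in BT-474 cells, an established human breast cancer line that carries extra copies of ERBB2, the gene for the receptor tyrosine kinase HER2, after transfection with HER2 siRNAs or with negative control siRNAs. It asked which mRNAs and which lincRNAs, long RNAs transcribed between protein-coding genes, differ in level after HER2 is silenced. Each group held 3 libraries of total RNA depleted of ribosomal RNA, and each library had an mRNA table and a lincRNA table of FPKM values. The mRNA tables held 23672 gene symbols, of which 18491 were above 0 in at least 1 library, and the lincRNA tables held 8263 loci, of which 3466 were. The number of reads per library is unknown. Relative depth was read from the steps that single reads leave in low FPKM values and set to 1 in control replicate 1. It was 0.841 and 1.21 in control replicates 2 and 3 and 1.66, 1.73 and 2.07 in HER2 siRNA replicates 1 to 3. By this estimate the HER2 siRNA libraries were on average 1.79 times as deep. The value of HER2 siRNA replicate 2 is less certain, with 68 of 444 compared genes at the step. That library had 15379 mRNAs above 0, fewer than control replicate 3 with 15932. Pearson's r of log2 values across tested mRNAs was 0.988 to 0.995 within groups and 0.924 to 0.930 between groups. For lincRNAs it was 0.830 to 0.924 within groups and 0.677 to 0.811 between them. The labels do not say that replicates were separate cultures, so p-values measure the spread between these libraries, which may be technical.

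ERBB2, the siRNA target, was lower in all 3 HER2 siRNA libraries than in all 3 control libraries. Its level was 113, 112 and 124 FPKM in control replicates 1 to 3 and 26.6, 24.9 and 28.1 FPKM in HER2 siRNA replicates 1 to 3. The mean was 116 ± 6.48 FPKM (SD, n = 3) in controls and 26.5 ± 1.58 FPKM (SD, n = 3) after HER2 siRNA, a level 4.38-fold lower. The log2 fold change of FPKM + 1 was -2.09 ± 0.08 (SE), with a limma adjusted p of 1.47e-07. A two-sided exact permutation test of the 6 values gave p = 0.1, the smallest that 3 against 3 libraries allow. Among the other receptors and ligands of the HER family, ERBB3, the kinase-impaired partner of HER2, rose from 12.9 ± 0.638 to 21.2 ± 0.958 FPKM (SD, n = 3; log2 fold change 0.68, limma adjusted p = 6.23e-05). TGFA, an EGFR ligand, fell from 1.53 to 1.14 FPKM (log2 fold change -0.24, limma adjusted p = 0.0166), a call that ended with upper-quartile scaling (limma adjusted p = 0.165) and without control replicate 3, HER2 siRNA replicate 1 or HER2 siRNA replicate 3 (0.0585, 0.0528 and 0.0601). BTC, another EGFR ligand, was at 2.03 ± 0.221 and 1.55 ± 0.275 FPKM and did not pass (limma adjusted p = 0.0540), though it did without control replicate 3 or HER2 siRNA replicate 3 (0.0365 and 0.0336). The other 11 of the 15 members, EGFR and ERBB4 among them, had a mean of 0.703 FPKM or less and were not tested. Adjusted over the list alone, 1 member rose and 3 fell.

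Genes that neighbour ERBB2 in 17q12-q21 did not move together. Of 11 tested neighbours, 3 rose, 2 fell and 6 did not pass, and the same numbers held when adjusted over the list alone. GSDMB rose from 11.9 to 22.5 FPKM, FBXL20 from 16.3 to 28.6 and ORMDL3 from 101 to 148, whereas PSMD3, a proteasome subunit gene, fell from 207 to 137 FPKM and IKZF3 from 3.72 to 2.83. The list as a whole did not pass (camera adjusted p = 0.202). With the other scalings more neighbours rose, 7 with quantile normalisation and 6 with upper-quartile scaling.

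**Figure D1:**
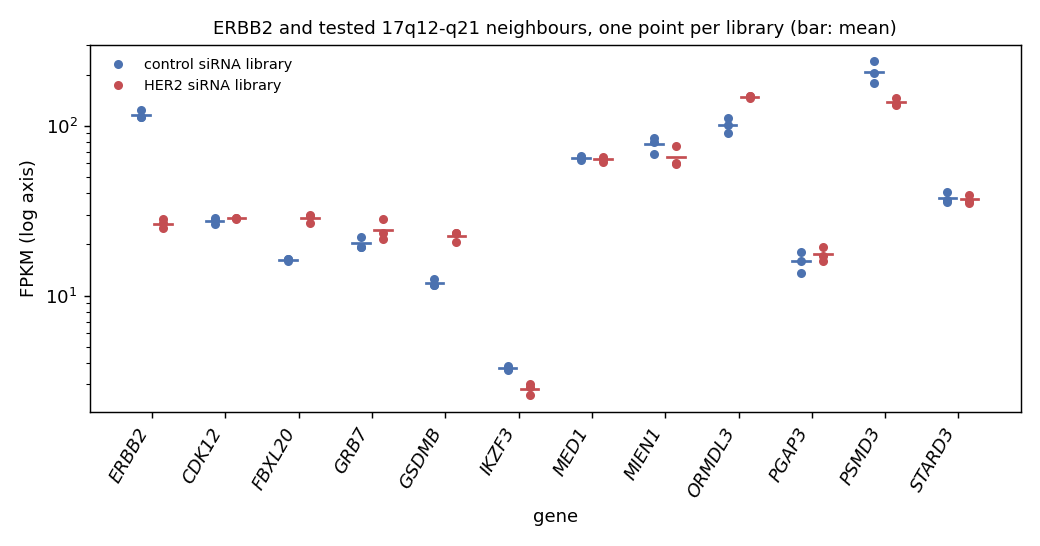
FPKM (log axis) of ERBB2 and its 11 tested 17q12-q21 neighbours, with 1 point per library, blue for control siRNA and red for HER2 siRNA, and bars at the group means. ERBB2 goes from a mean of 116 to 26.5 FPKM, while 3 neighbours rise, 2 fall and 6 do not pass the test.

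Across the transcriptome, all 31 tested genes of DNA replication, all 32 of mitosis and all 23 listed histones fell after HER2 siRNA, as did 20 of 23 genes of cholesterol synthesis and 13 of 16 of fatty acid synthesis, and 12 of 15 genes restrained by PI3K-AKT signalling rose while 1 fell. None of these list calls held when the correlation between genes was estimated, with adjusted p = 0.172 for mitosis and adjusted p = 0.226 for the others with an estimated correlation. SEPP1, which encodes selenoprotein P, had the largest rise on the log2(FPKM + 1) scale, though not as a ratio of FPKM, from 6.82 ± 0.913 to 50.2 ± 1.99 FPKM (SD, n = 3; log2 fold change 2.72, limma adjusted p = 8.11e-08). CST4, a salivary cystatin gene, rose from 1.46 to 10.9 FPKM, with a log2 fold change of 2.27, and shares sequence with its paralog CST1. CALCOCO1 rose from 2.64 to 14.01 FPKM, with a log2 fold change of 2.04. C6orf7 and LOC144481 rose by log2 fold changes of 2.36 and 2.24. The other 5 of the 10 largest rises were small RNA genes, SNORD9, SNORA20, SNORD8, RNU6-67 and MIR3609, whose FPKM values are less certain because the genes are short; MIR3609 rose from 1010 ± 140 to 4074 ± 911 FPKM. Of the 10 largest falls, 9 were replication-dependent histone genes, HIST1H3G, HIST1H1B, HIST1H3B, HIST1H2BE, HIST1H3F, HIST1H2AL, HIST1H2BI, HIST1H2BO and HIST1H2BB, with log2 fold changes from -3.98 to -3.09. These genes have near-identical copies, so the value of any single histone gene is uncertain. The other was PRR11, a gene of cell cycle progression, which fell from 35.0 ± 1.29 to 2.88 ± 0.0910 FPKM (SD, n = 3; log2 fold change -3.21, limma adjusted p = 3.55e-08).

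By limma on log2(FPKM + 1), 5210 of the 9345 genes tested in the mRNA tables (55.8%) passed, 1937 higher and 3273 lower, and 555 of them changed at least 2-fold on that scale, 109 higher and 446 lower. The groups did not overlap in 62.6% of tested genes, against 10% by chance. The split between directions depended on the scaling of the libraries: 37.2% of calls were higher with FPKM as deposited, 55.3% with quantile normalisation (3072 higher, 2488 lower) and 60.9% with upper-quartile scaling (3454 higher, 2219 lower). Those scalings moved the median log2 fold change of all tested genes, which was -0.08, by 0.12 and 0.16. Of the 3273 lower genes, 2478 were still called lower with quantile normalisation and 2219 with upper-quartile scaling. The 10 most abundant genes took 11.6% to 13.3% of the summed FPKM in control libraries and 16.9% to 19.4% in HER2 siRNA libraries.

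Genes of the cell cycle fell as a group. All 31 tested genes of the G1/S transition and DNA replication fell, with a median log2 fold change of -1.72. RRM2, a subunit gene of ribonucleotide reductase, fell from 23.7 ± 2.06 to 2.08 ± 0.169 FPKM (SD, n = 3), and PCNA, the replication clamp, from 100.1 ± 10.2 to 22.8 ± 0.187 FPKM. MCM10 went from 6.08 to 0.579 FPKM. All 32 tested mitosis genes fell, with a median log2 fold change of -2.42. TOP2A, the DNA topoisomerase of dividing cells, fell from 61.2 ± 0.268 to 7.88 ± 0.224 FPKM, TPX2, a spindle assembly factor, from 55.1 ± 1.18 to 8.20 ± 0.234, DLGAP5 from 25.5 to 3.35 and TTK, a spindle checkpoint kinase, from 24.1 to 3.31. All 23 listed replication-dependent histones fell, with a median log2 fold change of -2.50, while 22 fell with either other scaling, and HIST1H1D went from 252 ± 25.6 to 31.1 ± 1.94 FPKM and HIST1H2AB from 39.5 to 6.13. Adjusted over the list alone, the counts of the 3 lists were the same. Camera with a preset correlation of 0.01 called all 3 lists lower, with adjusted p of 1.14e-16, 2.75e-21 and 6.03e-13. None of the 3 calls held with a correlation estimated from the data: G1/S had adjusted p = 0.226 with an estimated correlation, mitosis adjusted p = 0.172 with an estimated correlation and histones adjusted p = 0.226 with an estimated correlation, and under the other camera settings the highest were 1.75e-10, 2.25e-17 and 3.02e-11.

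**Figure D2:**
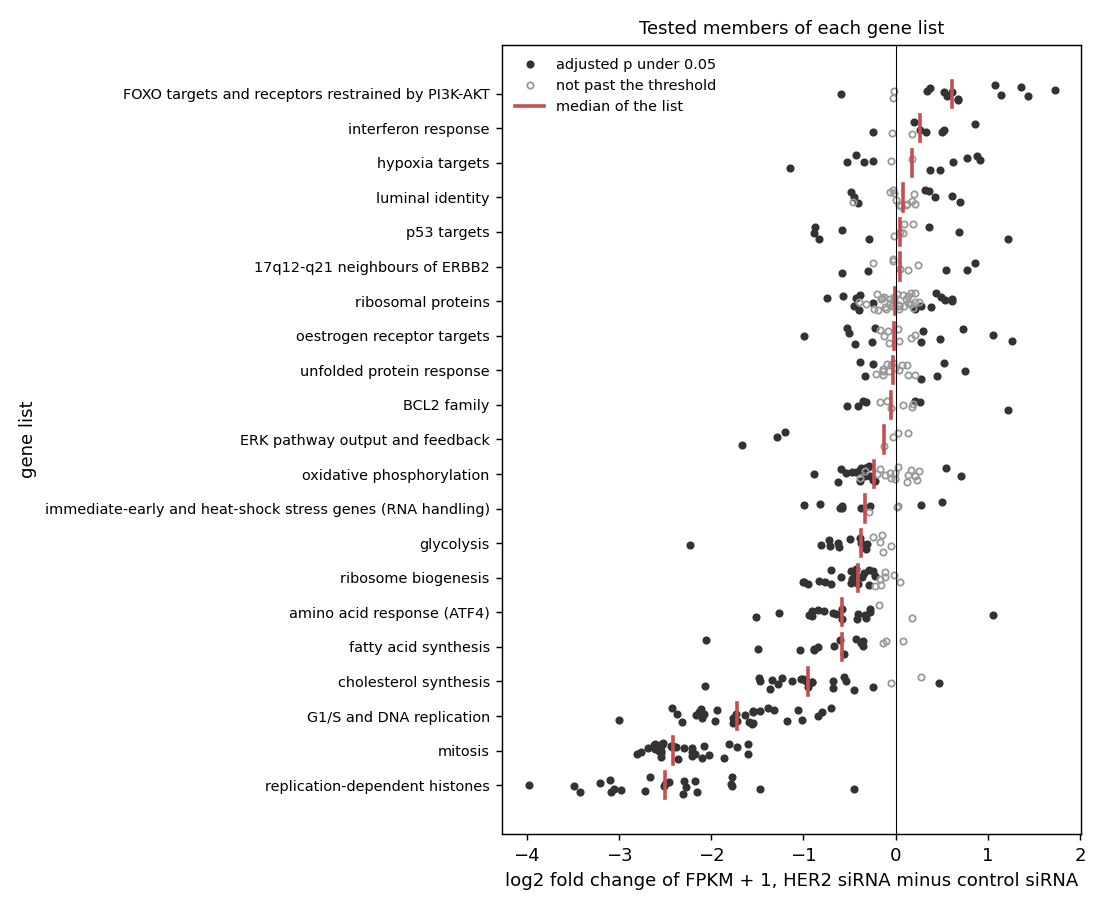
Log2 fold change of FPKM + 1 (HER2 siRNA minus control siRNA) for every tested member of the 21 gene lists with a list test, 1 point per gene, filled where the adjusted p was under 0.05, with a red bar at each list's median. All members of the G1/S (31), mitosis (32) and histone (23) lists lie below 0, and 12 of 15 members of the list restrained by PI3K-AKT rose.

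Genes of lipid synthesis fell as well. Of 23 tested cholesterol synthesis genes, 20 fell, 1 rose and 2 did not pass, with a median log2 fold change of -0.95; adjusted over the list alone, 20 fell and 2 rose. INSIG1, a sterol-regulated feedback gene, fell from 22.4 ± 1.23 to 4.57 ± 0.179 FPKM (SD, n = 3), HMGCS1, which makes HMG-CoA, from 37.3 to 12.8, IDI1 from 44.9 to 15.4 and MSMO1 from 17.1 to 6.06. The member that rose, named after its value was seen, was TM7SF2, a sterol reductase gene, from 23.3 to 32.7 FPKM. Of 16 tested fatty acid synthesis genes, 13 fell and 3 did not pass, with the same numbers when adjusted over the list alone. SCD, the stearoyl-CoA desaturase, fell from 31.4 ± 2.78 to 6.80 ± 0.766 FPKM, HSD17B12 from 18.0 to 5.77, FADS1, a fatty acid desaturase, from 6.21 to 2.91 and ACLY, which makes cytosolic acetyl-CoA, from 31.4 to 16.5. Camera called both lists lower (adjusted p = 1.92e-06 and 0.000269). Both had adjusted p = 0.226 with an estimated correlation, and at most 3.92e-05 and 0.00599 under the other camera settings.

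Genes of glycolysis, of the amino acid response driven by ATF4 and of ribosome biogenesis also fell. Among 16 tested glycolysis genes, 11 fell and 5 did not pass. LDHA, the lactate dehydrogenase A gene, fell most, from 75.0 ± 2.31 to 15.2 ± 1.13 FPKM (SD, n = 3), while GPI went from 17.9 to 11.3, PGK1 from 62.3 to 37.5 and ALDOA from 31.8 to 18.9. Of 20 tested genes of the amino acid response, 17 fell, 1 rose and 2 did not pass. PSAT1, of serine synthesis, fell from 13.0 to 3.91 FPKM, CEBPB from 4.23 to 1.18 and ASNS, the asparagine synthetase gene, from 10.2 to 4.98, whereas STC2 rose from 4.65 to 10.7. Of 27 tested ribosome biogenesis genes, 20 fell and 7 did not pass, with DDX21 going from 53.8 to 26.3 FPKM, NOP56 from 64.9 to 33.1, BOP1 from 3.25 to 1.14 and TCOF1 from 4.49 to 2.08. Adjusted over the list alone, the counts were the same except that 2 genes of the amino acid response rose. Camera called the 3 lists lower, with adjusted p of 0.00376, 0.000944 and 0.000359. Glycolysis had adjusted p = 0.486 with an estimated correlation, the amino acid response adjusted p = 0.290 with an estimated correlation and ribosome biogenesis adjusted p = 0.226 with an estimated correlation, and under the other camera settings the highest were 0.00962, 0.0130 and 0.0160. With quantile normalisation 8, 12 and 14 genes of these lists fell.

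Targets of FOXO factors and receptors restrained by PI3K-AKT rose. Of 15 tested members, 12 rose, 1 fell and 2 did not pass, with the same numbers when adjusted over the list alone and a median log2 fold change of 0.61. KLHL24 rose from 6.79 ± 0.461 to 24.8 ± 1.14 FPKM (SD, n = 3), FOXO3, a FOXO factor itself, from 3.59 to 9.14, PIK3IP1, an inhibitor of PI3K, from 3.68 to 11.6 and TNFSF10, which encodes the death ligand TRAIL, from 1.93 to 5.17. ERBB3 belongs to this list as well. The member that fell, named after its value was seen, was CDKN1B, the gene of the CDK inhibitor p27, from 26.2 to 17.03 FPKM. Camera called the list higher (adjusted p = 2.02e-06), with adjusted p = 0.226 with an estimated correlation and at most 0.000146 under the other camera settings. The interferon response list was called higher too (camera adjusted p = 0.0116): 6 of 9 tested members rose, 1 fell and 2 did not pass, also when adjusted over the list alone. This call had adjusted p = 0.290 with an estimated correlation and 0.0593 with no filter on low values, a filter at 5 FPKM left too few members to test, and the other camera settings kept it, at 0.00784 to 0.0298. IFI35 rose from 1.39 to 3.32 FPKM, HERC6 from 4.05 to 6.17, IFIH1, an RNA sensor gene, from 2.41 to 3.92 and STAT2 from 3.35 to 4.46. Of the 31 listed interferon genes, the untested ones had a mean of 0.918 FPKM or less.

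The list of ERK pathway output and feedback, with 7 of 20 members tested, was not called as deposited (camera adjusted p = 0.202, and adjusted p = 0.380 with an estimated correlation). Of the 7, 3 fell and none rose, also when adjusted over the list alone, and MYC rose with both other scalings. With no filter on low values camera called the list lower (adjusted p = 9.06e-05), and fry called it lower as well (adjusted p = 3.12e-05). DUSP6 and DUSP4, phosphatases induced by ERK, fell from 4.67 ± 0.0682 to 0.795 ± 0.185 FPKM (SD, n = 3) and from 9.07 to 3.13 FPKM, and CCND1, the cyclin D1 gene, fell from 45.2 to 19.1. MYC was at 13.2 ± 1.21 and 14.6 ± 1.13 FPKM and did not pass as deposited (limma adjusted p = 0.209). Of 20 tested oestrogen receptor targets, 6 rose and 6 fell as deposited, also when adjusted over the list alone, against 9 and 4 with quantile normalisation and 10 and 4 with upper-quartile scaling. PGR, the progesterone receptor gene, rose from 8.57 to 22.1 FPKM and STC2 rose as given above, while AGR2 fell from 289 to 145 and BCL2, an inhibitor of apoptosis, from 1.64 to 0.823. Of 20 tested genes of luminal identity, 5 rose and 3 fell, also when adjusted over the list alone, and 13 rose and 2 fell with upper-quartile scaling. The luminal list was not called as deposited (camera adjusted p = 0.0843, and adjusted p = 0.588 with an estimated correlation), whereas upper-quartile scaling and a filter at 5 FPKM called it higher (0.0461 and 0.0474), and over all camera settings the adjusted p ranged from 0.0461 to 0.588. CLDN3 rose from 1.28 to 2.48 FPKM, SCGB2A2, the mammaglobin gene, from 61.6 to 101, TFAP2C from 18.3 to 24.9, TOB1 from 20.7 to 26.1 and GATA3 from 4.44 to 5.99, while KRT18 fell from 239 to 174, KRT7 from 190 to 135 and TFAP2A from 2.81 to 1.84; the last 4 were named after their values were seen. The oestrogen receptor list had a camera adjusted p of 0.369.

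Markers of other cell types were mostly below the filter. Of 15 basal and myoepithelial markers only CDH3 was tested, at 1.04 ± 0.143 and 1.20 ± 0.178 FPKM (SD, n = 3), and it did not pass except with upper-quartile scaling. Of 21 mesenchymal and stromal markers, VIM was at 1.53 and 1.39 FPKM and did not pass, and TWIST1 rose from 4.02 ± 0.404 to 12.4 ± 1.23 FPKM (limma adjusted p = 2.86e-06), also when adjusted over the list alone. The remaining mesenchymal markers had a mean of 0.512 FPKM or less, and none of 19 immune cell markers exceeded a mean of 0.473 FPKM.

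Hypoxia targets, the unfolded protein response, the BCL2 family, p53 targets, ribosomal proteins, oxidative phosphorylation and the stress genes induced by RNA handling were not called, with camera adjusted p of 0.223, 0.302, 0.538, 0.696, 0.223, 0.369 and 0.293. Among 13 tested hypoxia targets, 6 rose and 5 fell, with MXI1 going from 1.64 to 3.84 FPKM, DDIT4 from 2.56 to 5.07, NDRG1 from 2.75 to 6.05 and EGLN3, an oxygen sensor gene, from 6.88 to 2.55. Of 21 genes of the unfolded protein response, 4 rose and 3 fell, and 9 rose with either other scaling. SEL1L rose from 12.9 to 22.4 FPKM, DNAJB9 from 3.00 to 4.78 and HSPA5, the chaperone BiP, from 28.8 to 39.5, while HYOU1 fell from 6.64 to 5.08. Of 13 tested BCL2 family genes, 3 rose and 4 fell as deposited, against 6 and 2 with quantile normalisation and 6 and 1 with upper-quartile scaling. BBC3, which encodes the pro-apoptotic protein PUMA, rose from 1.60 ± 0.338 to 5.03 ± 0.443 FPKM (SD, n = 3), BCL2L2 rose from 4.40 to 5.26 and BID fell from 4.42 to 3.24. Without control replicate 1, control replicate 3, HER2 siRNA replicate 1 or HER2 siRNA replicate 3, BCL2L2 did not pass (limma adjusted p of 0.0578, 0.0560, 0.0734 and 0.0803), nor did BID without control replicate 2 or HER2 siRNA replicate 1 (0.0590 and 0.0531) or with upper-quartile scaling, which also ended the call of HYOU1. Of 13 tested p53 targets, 3 rose and 5 fell as deposited, and 5 rose and 4 fell with either other scaling. TP53INP1 rose from 2.72 to 4.98 FPKM, MDM2, a negative regulator of p53, fell from 10.8 to 5.60 and CDKN1A, the CDK inhibitor p21, fell from 2.90 to 1.11. Among 46 ribosomal protein genes, many of which have processed pseudogenes, 8 rose and 7 fell as deposited, and 20 rose and 4 fell with upper-quartile scaling. RPL37 rose from 202 to 310 FPKM and RPL7 from 173 to 265, while RPLP0 fell from 398 to 237 and RPS2 from 213 to 143. Of 34 genes of oxidative phosphorylation, 16 fell and 2 rose as deposited, against 7 and 9 with quantile normalisation. ATP5G3 fell from 8.13 to 5.02 FPKM, ATP5G1 from 51.3 to 27.1, CYC1 from 39.2 to 25.1 and COX5A from 17.4 to 11.6. Of 12 tested stress genes, 7 fell and 2 rose. HSPH1 fell from 22.9 to 12.6 FPKM, HSPA8 from 532 to 268, JUN from 5.08 to 2.99 and DNAJB1 from 20.6 to 13.5. The counts of rises and falls were the same when adjusted over the list alone, except for 2 falls in the unfolded protein response, 6 rises and 5 falls among ribosomal proteins, 15 falls in oxidative phosphorylation and 8 falls among stress genes. The median, mean and camera direction differed in sign in 5 lists. Oestrogen receptor targets, the unfolded protein response and the BCL2 family had medians of -0.02, -0.03 and -0.05 and means of 0.06, 0.03 and 0.02, p53 targets a median of 0.05 and a mean of -0.06, and ribosomal proteins a median of -0.0045 and a mean of -0.0019, each with an upward camera direction.

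Of the long noncoding RNAs named in advance, 23 of 40 were tested in the mRNA tables, and 6 rose, 11 fell and 6 did not pass, also when adjusted over the list alone. DSCAM-AS1, a transcript of luminal breast cancer cells, rose from 3.61 ± 0.163 to 9.71 ± 0.623 FPKM (SD, n = 3) and EPB41L4A-AS1 from 4.60 to 10.5, while SNHG3 and SNHG1, hosts of small nucleolar RNAs, fell from 6.13 to 2.71 and from 21.7 to 9.96 FPKM. Antisense transcripts cannot be separated from overlapping genes here, because no strand setting is given in the sources used. With upper-quartile scaling 9 rose and 7 fell.

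In the lincRNA tables more loci rose than fell with FPKM as deposited. The locus XLOC_005772 rose from 1.02 ± 0.285 to 9.90 ± 0.663 FPKM (SD, n = 3; log2 fold change of FPKM + 0.1 of 3.19, limma adjusted p = 0.000510), and XLOC_005369 rose from 0.990 ± 0.861 to 6.17 ± 0.704 FPKM (log2 fold change 2.79, limma adjusted p = 0.0122). XLOC_000160 fell from 2.35 ± 0.755 to 0.501 ± 0.330 FPKM (log2 fold change -2.15, limma adjusted p = 0.0187), and XLOC_013852 fell from 1.38 ± 0.326 to 0.308 ± 0.143 FPKM (log2 fold change -1.91, limma adjusted p = 0.0122). XLOC_000160 lost its call with no filter on low values (limma adjusted p = 0.0684). The files do not pair these loci with gene names. Of 500 loci with a mean of at least 0.3 FPKM, 118 passed, 99 higher and 19 lower, 72 of them changed at least 2-fold, and the median log2 fold change was 0.39. With quantile normalisation 26 were higher and 33 lower, and with upper-quartile scaling 34 were higher and 25 lower, against 83.9% of calls higher as deposited. The number of higher loci was 43 without HER2 siRNA replicate 1, 38 without HER2 siRNA replicate 3 and 25 with no filter on low values, those changed at least 2-fold were 37, 36 and 27 in these fits and 9 with a pseudocount of 1, and leaving out any single library left 7 to 12 lower loci.

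**Figure D3:**
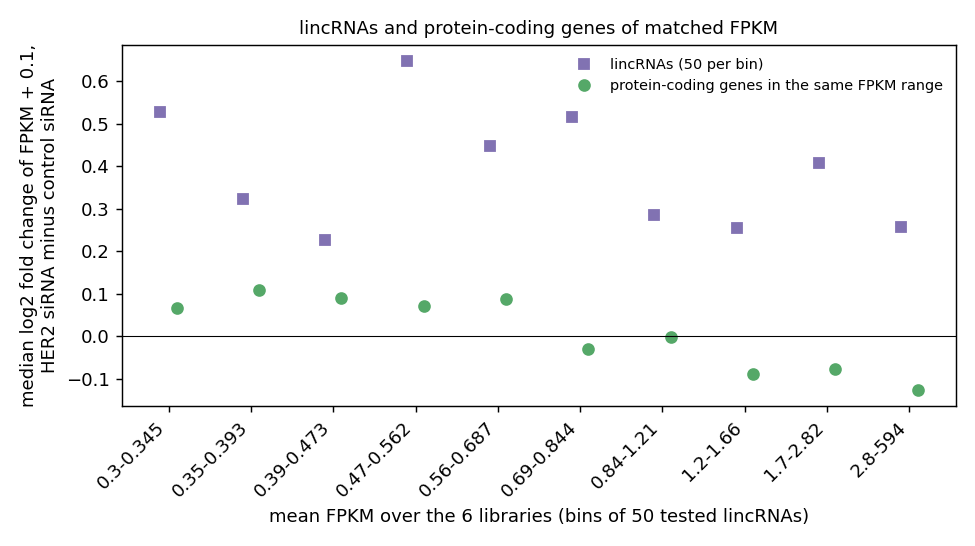
Median log2 fold change of FPKM + 0.1 (HER2 siRNA minus control siRNA) in bins of 50 of the 500 tested lincRNAs ordered by mean FPKM (x axis, range of mean FPKM in each bin), as squares, with protein-coding genes of the same FPKM range as circles. The lincRNA medians lie above 0 in every bin with FPKM as deposited, around the overall median of 0.39, and above those of the protein-coding genes.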

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

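Of the tests in this part, protein-coding genes alone and lincRNAs scaled by the mRNA upper quartile were chosen after the result was seen. ERBB2 stayed called in all alternatives, with log2 fold changes of -1.85 to -2.13. For mRNAs, 857 genes changed at least 2-fold with a pseudocount of 0.1. A filter at 5 FPKM, which tests fewer genes, gave 933 higher, 1952 lower and 364 changed at least 2-fold. Higher mRNAs numbered 3072 with quantile normalisation and 3454 with upper-quartile scaling, which move the centre of all genes. For lincRNAs, 9 changed at least 2-fold with a pseudocount of 1, which shrinks low values. No filter gave 25 higher, 2 lower and 27 changed at least 2-fold, and a filter at 1 FPKM gave 57, 9 and 27. Quantile normalisation gave 26, 33 and 29, upper-quartile scaling 34 higher and 34 changed at least 2-fold, a variance prior without a trend 12 lower (the cause was not tested), and the mRNA upper quartile 152 higher and 10 lower. Leaving out 1 library gave 38 to 78 higher, 7 to 12 lower and 36 to 69 changed at least 2-fold, with fewer libraries to test; without HER2 siRNA replicate 1 these were 43, 7 and 37, and without HER2 siRNA replicate 3 they were 38, 8 and 36.

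The replicate numbers did not consistently pair the libraries. Deviations from the group means of same-numbered libraries correlated at 0.25, -0.01 and 0.07 for mRNAs and 0.14, -0.12 and -0.12 for lincRNAs. For mRNAs and lincRNAs alike, replicate 1 correlated best with its own number, and replicates 2 and 3 did not. With the replicate number as a block, 2033 mRNAs were higher and 3448 lower, and 50 lincRNAs were higher, 15 lower and 47 changed at least 2-fold; the cause was not tested.

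With an estimated correlation camera called 0 gene lists, 3 had an unadjusted p under 0.05 and the lowest adjusted p was 0.172. The estimated correlations reached 0.607. Their size is not the only source of the higher p, since the ERK and stress lists had estimates of -0.110 and -0.0143, below the preset. The unadjusted camera p of these lists still went from 0.116 to 0.181 and from 0.223 to 0.269. What else raised it was not tested. The luminal list was gained with upper-quartile scaling and a filter at 5 FPKM, the ERK and stress lists with no filter and with fry, and the neighbours of ERBB2 with fry. p53 targets, with a median of 0.0489, turned to a downward direction with fry without passing. VIM, which did not pass, had 0.0465 with upper-quartile scaling and -0.157 to 0.0194 when 1 library was left out. Among the other values of named mRNAs, 12 lost and 7 gained a call and 1570 stayed on their side; for named lincRNAs 34 lost a call and 136 stayed; for lists 11 lost, 7 gained and 335 stayed. The HER2 siRNA libraries were 1.79 times as deep by the estimate from low FPKM values, in which case low control values carry more error.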

Other observations

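Of the tests in this part, those of a shared scaling error, of a uniform added background and of an FPKM error of short genes were chosen after the result was seen, as were the genes named here. Gene families given by symbol, some of which overlap the fixed lists, held many genes that passed the test. Of 19 tested nucleoporin genes with symbols in NUP, 18 fell, for example NUP205 from 24.2 ± 1.94 to 10.2 ± 0.245 FPKM and NUP188 from 10.5 to 5.43 (SD, n = 3), and 17 and 16 fell with quantile normalisation and upper-quartile scaling. Of 23 kinesin genes, 15 fell, led by the mitotic kinesins KIF23 and KIF2C, from 21.2 to 3.18 and from 19.7 to 3.21 FPKM, while KIF13B and KIF27 rose. With quantile normalisation 5 kinesin genes rose and 14 fell, and with upper-quartile scaling 5 rose and 13 fell. Of 339 ZNF genes, 132 rose and 46 fell, against 173 and 34 with quantile normalisation and 198 and 23 with upper-quartile scaling. Of 52 tested genes with symbols in HIST, 49 fell and none rose, and the family test that follows held the 47 matched as protein-coding, of which 44 fell. Among 51 symbol families tested together, HIST, NUP, KIF, RAD and UBE were called lower and ZNF higher by camera with the preset correlation. None were called with an estimated correlation (0 of 51, and 0 with an unadjusted p under 0.05, against 18 by fry), which leaves open whether families move together, because that test also called none of the fixed lists, the mitosis list with 32 of 32 members lower included.

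Protein-coding genes that rose included SOCS2, a feedback inhibitor of cytokine signalling, from 2.55 ± 0.373 to 10.97 ± 0.383 FPKM (SD, n = 3), CRYM from 10.8 to 36.2, HBP1, a transcriptional repressor, from 14.4 to 44.9, RBM20 from 2.73 to 9.95 and FBXO32, which encodes the ubiquitin ligase atrogin-1, from 2.01 to 7.37. Among small RNA genes, 25 of 73 microRNA genes rose and 7 fell, and 30 rose and 7 fell with upper-quartile scaling. FPKM at small RNA genes is less certain because the genes are short. It does not tell mature RNA from precursor or host transcripts. Some called values were at the floor: MIR374A, called higher, was at 0 FPKM in control replicate 3, and MIR3677, called lower, in all HER2 siRNA libraries. Small Cajal body RNAs were the only called members, 12 in number, of 19 genes of RefSeq type ncRNA, and all rose: SCARNA21 went from 274 ± 43.9 to 990 ± 339 FPKM and SCARNA9 from 23.5 to 52.2. With 10 splits of 3 against 3 libraries, the share of splits as large as the real one cannot fall under 0.05. The real split (1 of the 10) called 5210 mRNAs and 118 lincRNAs by limma, the highest other split 0 and 0, with at most 240 and 21 at an unadjusted p under 0.05. For gene lists the real split called 10 and the highest other split 10, in 3 splits with as many including the real one; these other splits mix libraries of both groups.

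The median lincRNA log2 fold change was 0.39 as deposited, but 0.13 with upper-quartile scaling of the lincRNA table itself and -0.0070 with its quantile normalisation. Both scalings by construction take out a shift of the whole table. Without rescaling, the median was 0.105 with no filter, 0.180 with a pseudocount of 1 and 0.274 with a filter at 1 FPKM. As deposited, protein-coding genes matched on mean FPKM and fitted the same way had a median of 0.000315 (10000 draws from -0.119 to 0.126). That value pools bins of mean FPKM: coding medians were 0.0667 to 0.109 in the bins below 0.687 FPKM and -0.125 in the top bin. LincRNA medians were higher than coding medians in every bin, at 0.226 to 0.647 in those below 0.687 FPKM. This gap argues against a shift of all weakly expressed genes as the whole source, though weakly expressed coding genes rose slightly. A scaling error shared by both tables is argued against by a median of 0.556 after division by the mRNA upper quartile, and greater depth acting through the log scale by 0.381 when values were averaged before the logarithm. Higher background remains open: the summed FPKM of 397 olfactory receptor genes, silent in most tissues, went from 2.30 ± 0.298 to 3.62 ± 1.03 (SD, n = 3), a log2 ratio of 0.658 that may reflect genomic DNA or precursor RNA (1.58-fold, 1.33-fold without HER2 siRNA replicate 2; exact permutation p = 0.1, the smallest possible). The median lincRNA gained 61.2 times as much FPKM as the mean olfactory receptor gene (0.205 against 0.00334 FPKM). This cannot decide on a uniform added background, since the lincRNAs had passed the filter at 0.3 FPKM and the olfactory receptor genes none. It also sets a median against a mean. An effect of HER2 siRNA on lincRNAs as a class cannot be separated here from a denominator of its own in the lincRNA tables.

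Small nucleolar RNAs (snoRNAs) went both ways, with 37 of 168 higher and 42 lower as deposited and 44 and 29 with upper-quartile scaling. Direction differed by class: among called snoRNAs paired with a host, symbols in SNORA mostly rose and symbols in SNORD mostly fell. Both classes had exceptions, such as SNORA61 (log2 fold change -0.61) and SNORD9 (2.30). Within the host NCL, SNORA75 had 1.05, against -1.85 for SNORD20 and -1.41 for SNORD82. The cause of this difference was not tested. If snoRNAs followed the gene that contains them, their changes would correlate with those of the hosts. Spearman's rho was 0.0655 and Pearson's r 0.0754 across 128 pairs with 67 hosts (permutation p = 0.46 for rho), and pairs of 1 host are not independent. Measured host levels thus explained little of the pooled changes. A relation within SNORA or SNORD genes was not tested, so the host as a source is not excluded. SnoRNAs of SNHG1, which fell (log2 fold change -1.05), were mostly lower, as were those of GAS5, which did not pass (0.07), whereas those of NCL went both ways. An FPKM error of short genes that differs between libraries stays open: of the called snoRNAs 53.2% moved the more frequent way, but that share restates the pattern, and other short genes went mostly upwards, 25 microRNA genes against 7 and all 12 called small Cajal body RNAs. Differences in processing or stability may remain and were not tested.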
